A study of Camellia sinensis with 9 samples.

How the data were processed

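RNA was measured in roots, flowers and leaves of the tea plant, Camellia sinensis, with 3 libraries for each tissue and 9 in all. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made after removal of ribosomal RNA, with no selection for polyadenylated RNA named, so non-coding and unspliced RNA can contribute to the values. Per the submitters' processing notes, HISAT2 (a spliced aligner), StringTie (a transcript assembler) and Cuffnorm (which estimates and scales transcript abundance) were used. Their versions, settings, strand setting and genome build are not given in the sources used here.

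The authors deposited a single table of FPKM values, fragments scaled by transcript length and library size, with 1 column per library and 1 row for each of 109879 assembled transcripts. Per the file headers, each transcript has a locus identifier, a strand, a start, an end and a class code. Class codes say how an assembled transcript lies against a reference annotation: the code = marks a match to a reference transcript, j a variant that shares a splice junction, u a transcript between annotated genes, and x a transcript opposite an annotated gene. The table gives no scaffold or chromosome name, so the positions printed are starts and ends along a scaffold that the table does not name. It pairs no identifier with a gene name or description. None of its identifiers (0 matches) occurred among the identifiers of the RefSeq gene table for the species, assembly ASM5576180v1. Loci are therefore given by identifier only. The 40 gene lists written before the data were examined (photosynthesis, catechin, caffeine and theanine metabolism, transport, pollen, microRNA target families and cell type markers among them) match on descriptions, so they could not be applied and no list was tested.

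Columns were matched to samples by title. 8 of the 9 columns carry a sample's title, and 1 leaf column carries a number, 23, that no leaf title has. By elimination this column is left for the title leaf 2, which the labels do not state. The column was used as a leaf replicate without a number and is called the unnumbered leaf library. The other libraries are called by the number in their title: root 13, 23 and 33, flower 1, 2 and 45, and leaf 1 and 41. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The highest share of tested loci with an identical value above 0 in a pair of libraries was 0.00275%, so no library was treated as deposited more than once. No column of per-sample values was left unused (0).

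The values were computed from the authors' FPKM as follows. The FPKM of all transcripts of a locus were summed, giving 61592 loci, of which 42483 hold 1 transcript. The assembly joined neighbouring reference models in places, since 4273 loci hold 2 or more reference transcripts. Loci with an FPKM of at least 1 in at least 3 libraries were tested (36342 loci). The test was limma (version 3.58.1, R 4.3.3) on log2(FPKM + 1) with a trend of the variance on expression, 1 mean for each tissue and a spread shared by all 9 libraries (6 residual degrees of freedom). A locus was called when its Benjamini-Hochberg adjusted p was under 0.05 and its difference was at least 1 on the log2(FPKM + 1) scale, which understates the change of loci with low values. A locus was tissue-enriched when it was called higher in that tissue than in both others. Loci were classed as annotated (holding a reference transcript), intergenic (all transcripts coded u), antisense (holding a transcript coded x and no reference transcript) or other. Class shares were compared with Fisher's exact test, two-sided, over tested loci, which are not independent replicates. Named loci follow a rule fixed before the data were examined: for identifiers without descriptions, the 2 loci with the largest difference in each direction of each comparison among called loci whose groups do not overlap, and the 3 loci with the highest mean in each tissue.

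Depth, here the number of fragments that 1 FPKM stands for, was read from the values. It depends on how the FPKM were scaled as well as on how many fragments were sequenced. In loci of 600 to 3000 nt with 1 transcript and no strand, taken as single-exon, the low FPKM values lay on steps. After a length correction fitted in each library (195 to 211 nt), 100% of the values between 1.5 and 10 fragments came out within 0.05 of a whole number, where chance would give 10%. At a length of 1000 nt, 1 fragment was worth between 0.0385 FPKM (leaf 1) and 0.0715 FPKM (root 23), so 1 FPKM stood for 14.0 to 25.9 fragments and a count of 0 allows up to 0.116 to 0.215 FPKM (3 fragments). These limits cover counting error only. Fragment counts of multi-exon loci could not be recovered, so no count test was run. Many values are not 0 but far below 1 fragment, as isoform estimates give (13.1% to 15.1% of transcripts per library lay between 0 and 0.001 FPKM), and such values were not read as expression.

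The fit was tested on simulated data with the real loci (36342), spreads and overall means, and 200 changed loci for each comparison. The changed loci were drawn only from those with a mean of at least 2 on the log2(FPKM + 1) scale, so recovery at lower loci was not measured. For root against leaf it recovered 1 of 50 loci changed by 2-fold, 25 of 50 changed by 4-fold, 39 of 50 changed by 8-fold and 45 of 50 changed by 16-fold, with 3 false calls. Flower against leaf gave 1, 28, 40 and 45 of 50 with 3 false calls, and flower against root 1, 26, 39 and 44 of 50 with 7. These changes were set on the log2(FPKM + 1) scale, and the counts recovered were the same without the fold threshold. Only 200 loci were changed, where 14563 to 17946 loci had an adjusted p under 0.05 (limma) in the data. With so few changed loci that threshold is harder to reach, so the shares recovered are not the sensitivity of the real test. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and FPKM of at least 5), the scaling (quantile normalization, each library scaled to an equal sum, and TMM factors), the variance model, array weights, the fold threshold, the compared tissues alone and each library left out in turn. 3 further alternatives were chosen after seeing the data: leaving out loci spanning under 400 nt, reference transcripts alone, and transcripts in place of loci. For the intergenic share, leaving out MSTRG.10187 and MSTRG.24705, the 3 highest root loci, or loci spanning under 400 nt was also chosen after seeing the data, as was leaving out loci spanning under 400 or 1000 nt for the class odds ratios. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the depth estimate and the plots.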

Results

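Transcript abundance was measured in roots, flowers and leaves of Camellia sinensis, the evergreen shrub whose young leaves are made into tea and whose tissues accumulate catechins, caffeine and theanine. The series title places these libraries in a study of microRNAs and their targets in different organs. The small RNA data were not analysed here. The assembly held 109879 transcripts, of which 36951 (33.6%) matched reference transcripts, 29200 (26.6%) were splice variants of annotated genes, 36531 (33.2%) lay between annotated genes and 1764 (1.61%) lay opposite an annotated gene. An FPKM of at least 1 was reached by 28278 ± 477 loci in root, 28847 ± 382 in flower and 29788 ± 521 in leaf (SD, n = 3 each). Depth, the number of fragments that 1 FPKM stands for, was highest in leaf libraries. Relative to the geometric mean of all libraries, it was 1.25 to 1.41 in leaf. In root it was 0.759 to 0.968 and in flower 0.765 to 0.973. It depends on the scaling of the FPKM as well as on the fragments sequenced, so it does not show that leaf was sequenced deeper. Summed FPKM ran from 623826 in leaf 1 to 1250929 in flower 1.

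Libraries of a tissue resembled each other more than those of other tissues. Over the 36342 tested loci, Pearson's r of log2(FPKM + 1) was 0.92 to 0.97 within root, 0.87 to 0.95 within flower and 0.82 to 0.97 within leaf. Between tissues it was 0.45 to 0.53 for root and flower, 0.49 to 0.63 for flower and leaf, and 0.51 to 0.67 for root and leaf. These correlations are across loci, which are not independent replicates. Leaf 41 and flower 2 stood apart most within their tissues, and root 13 did so less. Root 13 had a correlation of 0.92 with root 23 and with root 33, where those reached 0.97 with each other. Flower 2 had a correlation of 0.87 with flower 1 and 0.88 with flower 45, where those libraries reached 0.95 with each other. For leaf 41, the correlation with each of the other leaf libraries was 0.82, where those reached 0.97 with each other. Its correlation with root reached 0.67, where theirs reached 0.54.

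**Figure D1:**
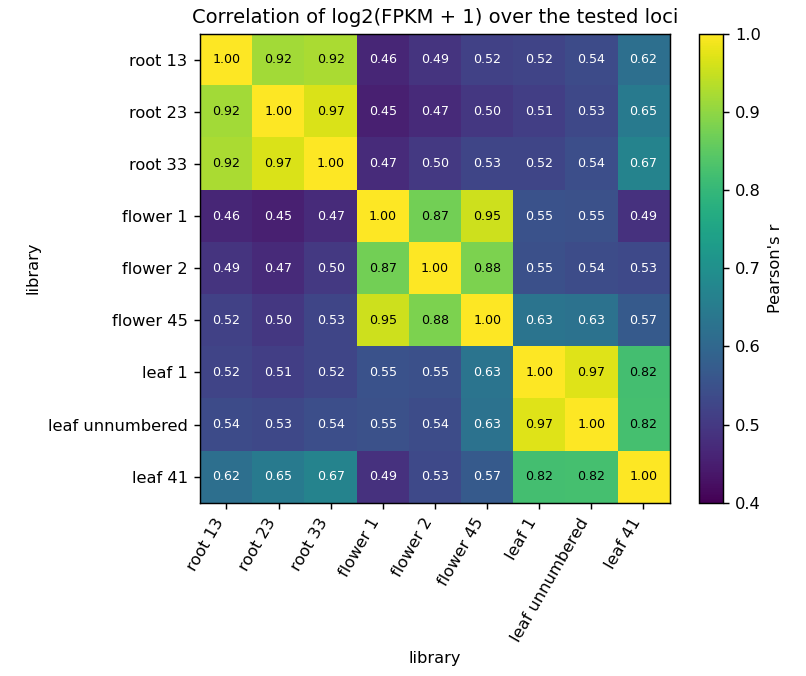
Pearson's r of log2(FPKM + 1) between each pair of the 9 libraries over the 36342 tested loci; rows and columns are libraries and the color scale runs from 0.4 to 1. Leaf 41 reaches 0.67 with root, above the 0.54 reached by the other leaf libraries.

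The most abundant loci differed between the tissues. In root, the highest means belonged to 3 intergenic loci: MSTRG.10187 (positions 194222 to 194425) at 23803 ± 11500 FPKM, MSTRG.24705 (positions 55622 to 55822) at 11477 ± 4872 FPKM, and MSTRG.23291 (positions 93 to 3218) at 7357 ± 2654 FPKM (SD, n = 3). The first and second span 204 and 201 nt, close to the fitted length correction, where FPKM rests on a very short effective length. In flower, MSTRG.25156 (reference transcript CSA019025.1, positions 141085 to 141366) stood at 7921 ± 1147 FPKM, followed by MSTRG.24823 (CSA034913.1, positions 141625 to 141858) at 7770 ± 3661 FPKM and the intergenic MSTRG.24822 (positions 139575 to 140714) at 7399 ± 3614 FPKM. MSTRG.25156 spans 282 nt and MSTRG.24823 less, so their ranks also rest on short effective lengths. MSTRG.24822 and MSTRG.24823 have consecutive numbers and lie on the plus strand. Their values in FPKM were close: 11136 and 11643 in flower 1, 3921 and 4367 in flower 2, 7142 and 7298 in flower 45. Whether they are parts of 1 gene was not tested. In leaf, MSTRG.16967 (CSA004763.1, positions 247513 to 250275) stood at 13560 ± 5244 FPKM, MSTRG.1387 (CSA008917.1, positions 1432177 to 1432962) at 9061 ± 3158 FPKM, and the intergenic MSTRG.45264 (positions 109591 to 109976) at 7854 ± 2591 FPKM. The 10 highest loci of each library took 8.56% ± 1.60 of summed FPKM in root, 5.88% ± 0.981 in flower and 9.15% ± 0.983 in leaf (SD, n = 3).

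Root was compared with leaf, the below-ground organ with the photosynthetic one. Of the 36342 tested loci, 7207 were higher and 5621 lower in root. Among these, 1661 were higher and 1302 lower by at least 8-fold. Annotated loci gave 4065 of the higher and 3425 of the lower calls, intergenic loci 2873 and 1991, and antisense loci 143 and 114. The loci with the largest excess in root were the intergenic MSTRG.18954 (positions 38672 to 83105, plus strand), at 3220 ± 30.1 FPKM in root and 0.412 ± 0.129 in leaf, and MSTRG.12400 (CSA011023.1, positions 348851 to 411143, plus strand), at 3137 ± 1116 and 0.436 ± 0.281 FPKM (SD, n = 3). Their differences were 11.16 ± 0.29 and 11.05 ± 0.28 (SE) on the log2(FPKM + 1) scale, each with a limma adjusted p of 1.5e-07. The loci with the largest excess in leaf were MSTRG.16967, which stood at 3.77 ± 0.0745 FPKM in root and differed by -11.40 ± 0.43 (adjusted p = 8.82e-07, limma), and MSTRG.15151 (CSA004909.1, positions 153830 to 157376, minus strand), at 1.49 ± 0.445 FPKM in root and 3612 ± 2361 in leaf, which differed by -10.18 ± 0.57 (adjusted p = 4.57e-06, limma). The groups did not overlap at 54.1% of tested loci, where chance gives 10% for 3 libraries against 3. With each library scaled to an equal sum the balance turned, to 5637 higher and 8033 lower, and the median difference over all loci moved from 0 to -0.28. Without leaf 41 the calls were 7960 higher and 7068 lower.

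Flower was compared with leaf. In flower, 7375 loci were higher and 6301 lower. With the authors' scaling the larger changes lay mostly on the higher side: 2162 loci were higher and 864 lower by at least 8-fold. The 8-fold counts were not taken under another scaling. Annotated loci gave 4740 higher and 3921 lower calls, intergenic loci 2365 and 2163, and antisense loci 159 and 133. MSTRG.34312 (CSA001062.1 and CSA001063.1, positions 16213 to 55073, minus strand) stood at 5401 ± 746 FPKM in flower and 0.648 ± 0.601 in leaf, a difference of 11.73 ± 0.33 (adjusted p = 6.43e-07, limma). MSTRG.25156 stood at 1.56 ± 0.114 FPKM in leaf and differed by 11.59 ± 0.34 (adjusted p = 6.43e-07, limma). Leaf exceeded flower most at MSTRG.22912 (CSA025445.1, positions 277040 to 278230, minus strand), with 2134 ± 1439 FPKM in leaf and 1.05 ± 0.350 in flower, and at MSTRG.45920 (CSA013997.1, positions 92597 to 97858, plus strand), with 4469 ± 843 and 4.31 ± 2.48 FPKM. Both differed by -9.80, with SE of 0.69 and 0.63 and limma adjusted p of 1.41e-05 and 1.02e-05. The groups did not overlap at 51.5% of tested loci (10% by chance). With equal sums, 5540 loci were higher and 9332 lower, with a median difference of -0.38 in place of -0.02, so whether more loci are higher in flower or in leaf depends on the scaling. Without flower 2, 7643 loci were higher and 6087 lower.

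Flower was also compared with root, which gave the most calls of the 3 comparisons. In flower, 7931 loci were higher and 8192 lower than in root, and 2366 were higher and 1712 lower by at least 8-fold. Annotated loci gave 4969 higher and 4469 lower calls. Intergenic loci gave 2670 higher and 3414 lower calls, and antisense loci 170 and 174. MSTRG.47179 (CSA035864.1, positions 12410 to 15952, plus strand) stood at 5466 ± 2589 FPKM in flower and 0.552 ± 0.179 in root, a difference of 11.67 ± 1.18 (adjusted p = 5.78e-05, limma). Its SE also draws on the leaf libraries, where it stood at 63.8 FPKM in leaf 41 and at 0.733 and 0.973 in the others. Without leaf 41 the adjusted p was 6.63e-07 (limma). MSTRG.25156 differed by 11.53 ± 0.34 from its 1.89 ± 1.31 FPKM in root (adjusted p = 2.25e-07, limma). Root exceeded flower most at MSTRG.10178 (CSA002827.1, positions 591900 to 592517, plus strand), with 2501 ± 237 FPKM against 0.893 ± 0.595, a difference of -10.42 ± 0.27 (adjusted p = 2.10e-07, limma). The intergenic MSTRG.47335 (positions 37255 to 38293, minus strand) followed with 2990 ± 1921 FPKM in root and 1.27 ± 1.20 in flower, a difference of -10.15 ± 0.62 (adjusted p = 3.99e-06, limma). The groups did not overlap at 60.6% of tested loci (10% by chance). The near-even balance turned under several settings: without flower 2, 8434 loci were higher and 8111 lower, with array weights 9222 and 9100, with a filter of FPKM 5 they were 5757 and 5523, and with a pseudocount of 5 they were 5239 and 4668.

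In all 3 comparisons a pseudocount of 5 in place of 1, which shrinks differences between low values, left fewer calls: 7429 for root and leaf, 8204 for flower and leaf, and 9907 for flower and root.

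**Figure D2:**
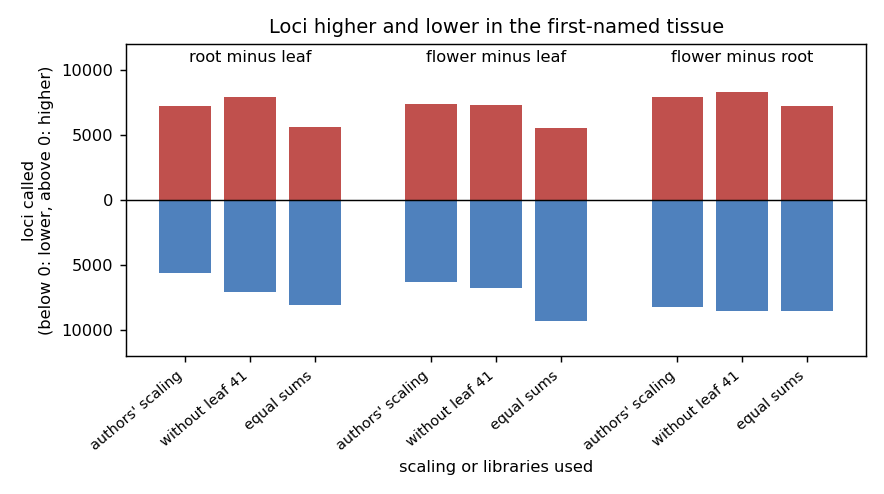
Loci called higher (above 0) and lower (below 0) in the first-named tissue of each comparison, with the authors' scaling, without leaf 41 and with each library scaled to an equal sum. Equal sums turn root minus leaf from 7207 higher and 5621 lower to 5637 higher and 8033 lower.

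**Figure D3:**
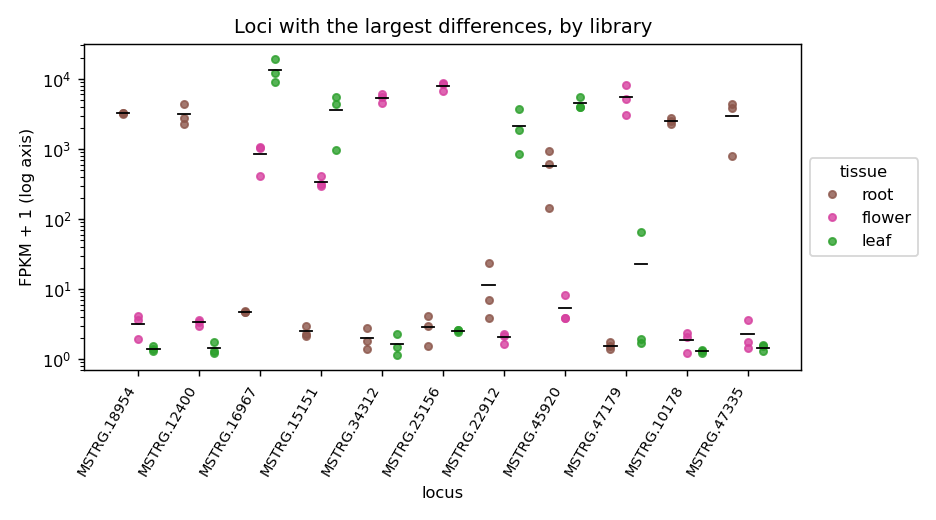
FPKM + 1 (log axis) of the loci with the largest differences in each direction; points are single libraries colored by tissue and black lines are means of 3 libraries. MSTRG.18954 lies near 3220 FPKM in every root library and below 1 FPKM in leaf.

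Loci higher in a single tissue than in both others were counted next. Flower had 5143 enriched loci (14.2% of those tested), root 4889 (13.5%) and leaf 2983 (8.21%). Of these, 1555 in flower, 1070 in root and 547 in leaf exceeded both other tissues by at least 8-fold. The median mean level of the enriched loci in their own tissue was 26.0 FPKM in flower, 16.3 in root and 13.5 in leaf. Each set is the overlap of calls from comparisons that share libraries. Independent lists of the same lengths would share 1609.5 loci for flower, 1624.6 for root and 974.6 for leaf. Unchanged groups simulated with the same spread gave at most 0 in 20 simulations. A count near 0 is set in advance there by the threshold on adjusted p, so it does not tell tissue from library differences. The order of the tissues is not firm. Without leaf 41 the counts were 4958 in flower, 5469 in root and 3797 in leaf, and with equal sums they were 4168, 4188 and 4543. Without flower 2 they were 5391, 4865 and 2937.

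Transcript classes took different shares of summed FPKM in the libraries of each tissue. Intergenic transcripts held 23.9% ± 0.144 of summed FPKM in root, 21.2% ± 1.28 in flower and 17.3% ± 0.961 in leaf (SD, n = 3), and no tissue overlapped another. The excess of root over flower rested on MSTRG.10187 and MSTRG.24705, the loci of 204 and 201 nt: without them the shares were 21.1% ± 0.779 in root, 21.1% ± 1.32 in flower and 17.1% ± 0.847 in leaf. Without all loci spanning under 400 nt they were 20.2% ± 0.754, 20.6% ± 1.38 and 15.2% ± 0.862, and leaf still overlapped neither of the others. Without the 3 highest root loci the shares were 20.5% ± 0.940 in root, 21.1% ± 1.32 in flower and 17.0% ± 0.800 in leaf. These settings were chosen after seeing the data. Antisense transcripts held 2.24% ± 0.0856 in flower, 1.55% ± 0.115 in root and 1.19% ± 0.135 in leaf, again without overlap. Splice variants held 30.5% ± 1.32 in leaf, 28.7% ± 0.317 in root and 26.4% ± 1.03 in flower. Over all loci, each of these contrasts had p = 0.1 in an exact two-sided permutation test, the smallest that 3 libraries against 3 allow, and 0.12 after Benjamini-Hochberg adjustment over 18 such contrasts, so none can pass a threshold of 0.05. The use of strand in the counting is not stated, so reads of an antisense transcript and of the gene opposite it may not have been told apart.

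Enriched loci were split unevenly between classes. Of the 15141 tested intergenic loci, 14.8% were root-enriched, against 12.4% of the 19796 annotated loci (odds ratio 1.22, 95% interval 1.15 to 1.30, adjusted p = 3.71e-10, Fisher's exact test). Flower enrichment was rarer among intergenic loci, at 11.6% against 16.1% (odds ratio 0.684, 95% interval 0.642 to 0.729, adjusted p = 2.10e-32, Fisher's exact test), as was leaf enrichment, at 7.30% against 8.93% (odds ratio 0.803, 95% interval 0.742 to 0.869, adjusted p = 7.32e-08, Fisher's exact test). The 785 antisense loci did not differ detectably from annotated loci: 13.4% were root-enriched (odds ratio 1.09, 95% interval 0.876 to 1.35), 15.4% flower-enriched (0.950, 0.773 to 1.16) and 7.90% leaf-enriched (0.875, 0.661 to 1.14). Intergenic loci were lower and shorter than annotated ones, with medians of 2.23 against 10.3 FPKM and spans of 1166 against 5819 nt. Within strata of span the root odds ratio was 0.929 (95% interval 0.865 to 0.999), so the excess in root does not hold among loci of like span, while the flower odds ratio was 0.637 (0.592 to 0.686) and the leaf odds ratio 0.848 (0.774 to 0.929).

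**Figure D4:**
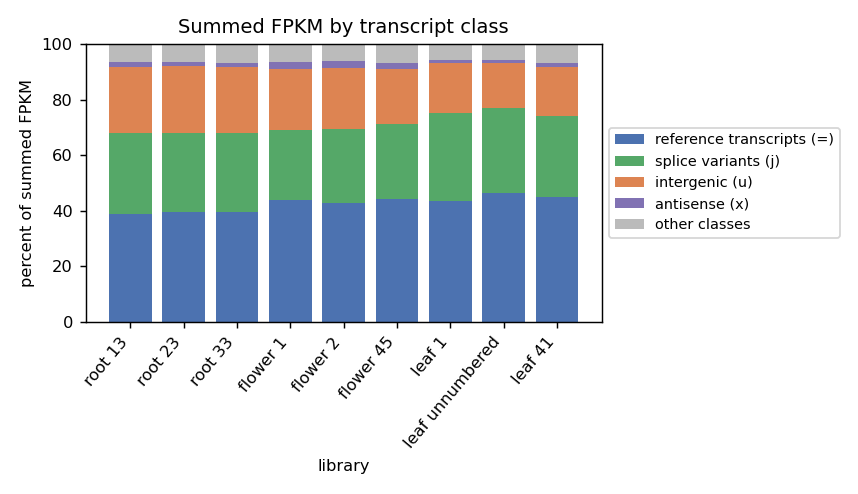
Percent of summed FPKM held by each transcript class in the 9 libraries; each bar is a library and the letters are class codes. Intergenic transcripts hold 23.9% in root, 21.2% in flower and 17.3% in leaf on average, and 21.1%, 21.1% and 17.1% without MSTRG.10187 and MSTRG.24705.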

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

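The settings that leave out loci spanning under 400 nt, use reference transcripts alone or use transcripts in place of loci were chosen after seeing the data. Over 15 alternatives to the processing, 77 of the 90 counts of called or enriched loci stayed within 1.5 times the reported count. All 54 counts with a library left out in turn did so too. With transcripts in place of loci, the 90 include counts of transcripts (55806 tested), which are not counts of the same thing. Some settings tested far fewer or more loci than the 36342 of the main fit. Such counts can move with the number tested, so the 1.5-fold range does not by itself show a result kept or lost. The loci named for their differences kept their direction and an adjusted p under 0.05 (limma) in all 272 values computed; the loci named for their mean in a tissue alone were not run under the alternatives. With a pseudocount of 5 the calls were 7429 for root minus leaf, 8204 for flower minus leaf and 9907 for flower minus root, with 3041 root-enriched and 1746 leaf-enriched loci; a larger pseudocount shrinks differences between low values by construction. A filter of FPKM 5 gave 1806 leaf-enriched loci among 20545 tested. Equal sums gave 4543 leaf-enriched loci, which include all 2983 reported ones; leaf libraries had the lowest summed FPKM, so this scaling raises them. Reference transcripts alone, with 12900 loci tested, gave 4765, 5217 and 6022 calls for root minus leaf, flower minus leaf and flower minus root, and 1718 root-enriched, 2078 flower-enriched and 1009 leaf-enriched loci. Of the reported calls among the loci tested there, 4428 of 5284, 4996 of 5975 and 5539 of 6518 were kept, and 9, 11 and 26 turned to the opposite direction. Quantile normalization moved the median difference of flower minus leaf to -0.12 and gave 6410 higher and 7075 lower calls. No paired analysis was possible because the flower and leaf columns share only 1 replicate number, the second leaf title having no column of that number. The planned tests of gene lists were not run because no identifier has a description, and the planned count tests were not run because the table holds no counts. Depth limits low loci: at 1000 nt, 3 fragments correspond to 0.116 to 0.215 FPKM. The limit is higher in shorter loci, where 1 fragment is worth more FPKM. For the 3420 tested loci spanning under 400 nt, the filter of FPKM 1 can therefore lie near it.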

Other observations

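The tests on leaf 41 and those without short loci were chosen after their results were seen. The tests on transcript classes were chosen after the class shares were seen, and those on leading transcripts and neighbouring loci after the table's columns were seen.

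Some loci had a different leading transcript in different tissues. The leading transcript of a locus, the one with the highest FPKM, was compared among loci with 2 or more transcripts and an FPKM of at least 1 in all 6 libraries of a comparison. One transcript led in all 3 libraries of the first tissue and another in all 3 of the second at 471 of 11054 loci (4.26%) for flower and root, 370 of 12028 (3.08%) for root and leaf, and 184 of 11414 (1.61%) for flower and leaf. At 272, 231 and 92 of these loci the summed level of the locus was not called different, which does not show that it was equal. A reference transcript and a splice variant exchanged the lead at 184, 119 and 67 loci, and different reference models joined in a locus did so at 7, 9 and 13. The real grouping gave the largest count in 1 of the 10 splits of each set of 6 libraries. The highest of the other splits gave 82 for flower and root, 178 for root and leaf and 55 for flower and leaf, and 10 splits are too few for a share under 0.05. The split with 178 put leaf 41 on the side of root 23 and root 33.

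Leaf 41 stood apart from the other leaf libraries towards root. It held 718 loci at 10 FPKM or more and at 4 times or more the other leaf libraries. Of these, 490 (68.2%) were at least 2-fold higher in root than in those libraries, and 356 (49.6%) in flower; choosing loci that are low in those libraries raises both shares. Among unraised loci of like level in those libraries that reached 10 FPKM in leaf 41 or in the mean of root or flower, the share was 50.9% for root and, unlike among the raised loci, higher for flower. At 460 of the 718 (64.1%) leaf 41 also exceeded the root mean. Root RNA mixed into the library would lift every root transcript by a common fraction. A set of 232 loci was high in root and near 0 in flower and the other leaf libraries. In leaf 41 they reached a median of 0.250% of the root level. Their upper quartile was 3.49% and their 95th percentile 23.1%, which argues against a common fraction above a few percent. A smaller fraction is not excluded. The 3 highest root loci were also higher in leaf 41 than in the other leaf libraries, as MSTRG.10187 at 1814 FPKM against 97.4 and 65.5. The 490 loci would need a median of 90.2% of the root level (lower quartile 35.7%). Choosing loci raised 4-fold in leaf 41 sets part of that need in advance, so it cannot decide. A root library under a leaf label is argued against: the lowest correlation of leaf 41 with leaf was 0.8197, above its highest with root, 0.6684. Leaf 41 had a relative depth of 1.264, between those of the other leaf libraries (1.249 and 1.409). Since that depth depends on the scaling of the FPKM, it cannot decide whether a difference in the fragments sequenced played a part. A leaf of another age or condition stays open, since the labels give neither, and was not tested.

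Intergenic loci were more often root-enriched and less often flower-enriched than annotated loci. Their lower expression is argued against as the whole cause, since within 10 strata of mean expression the odds ratios stayed at 1.248 for root and 0.7752 for flower, and the scaling is argued against by odds ratios of 1.380 and 0.7585 with equal sums. Span separates the parts: within strata of span the flower odds ratio was 0.6371, but the root odds ratio was 0.9294, so the root excess is not seen among loci of like span, and span is a candidate explanation for it. The shortest loci alone do not account for it, since the root odds ratio was 1.24 (95% interval 1.16 to 1.32) without loci spanning under 400 nt and 1.23 (1.14 to 1.33) without those under 1000 nt. Leaf enrichment was also rarer among intergenic loci, with odds ratios of 0.681 within strata of expression, 0.848 within strata of span and 0.786 with equal sums. Without leaf 41 the odds ratios were 1.30 for root, 0.685 for flower and 0.832 for leaf. A difference between the tissues in unannotated RNA stays open for flower and leaf, as a hypothesis.

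Intergenic loci next to an annotated locus on the same strand tended to share its profile across the 9 libraries. Neighbours were taken from consecutive locus numbers with rising positions, since scaffolds are not named. In 347 pairs within 1000 nt the median correlation was 0.3859, above the highest of 1000 random pairings of the same loci (0.155), which argues against chance pairing for the 347 pairs as a set. The 80 pairs without a strand had a median of 0.300. The 112 same-strand pairs had a median of 0.585 and the 155 opposite-strand pairs 0.142 (below the highest random pairing), a difference of 0.4429 (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest they can give), and beyond 20000 nt both medians were near 0 (0.00636 and -0.0153). A candidate explanation is that some same-strand intergenic loci are unjoined parts of the neighbouring gene, such as an untranslated region missing from the annotation. Tandem copies of a gene, which also share strand and profile, were not tested and stay open.

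Other splits of the libraries bear on the counts of called loci. For root minus leaf the real grouping gave 12828 calls and the highest other split 148, for flower minus leaf 13676 and 1, and for flower minus root 16123 and 1; the real grouping was the largest, 1 of 10 splits each time, and 10 splits are too few for a share under 0.05. The split with 148 calls also put leaf 41 with root 23 and root 33. For enriched loci, 99 random splits of the 9 libraries into 3 groups and the real one were fitted. For root, 1 of 100 splits gave a count as large as the real one (4889, highest other 4181). For flower it was 1 of 100 (5143, highest other 3779) and for leaf 4 of 100 (2983, highest other 4130). These shares cannot exclude chance, since a split that mixes tissues widens the spread within groups and so gives few calls. For leaf, the 3 other splits with a count as large all kept a whole tissue together. The high counts of other splits came from those that kept a whole tissue together; among the rest the highest were 27, 16 and 3.

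Loci at 10 FPKM or more in a single library and at least 5 times every other library numbered 263 in flower 2, 128 in leaf 41, 114 in root 13 and 54 in flower 1, and between 8 and 13 in each of the other libraries.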
